A study of Mus musculus with 4 samples.

How the data were processed

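Bulk ATAC-seq was performed on nuclei of mouse colonic organoids that had been treated, frozen and thawed, per the labels' protocols. There were 4 libraries, 1 in each of 4 groups (colitis or control, each with T-5224 or DMSO), and the labels give all the same batch. The labels do not say that any library has a replicate, so no spread between cultures or animals can be given.

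The deposited data were 1 peak list for the series in the narrowPeak format. Bowtie2, MACS2 and the genome build mm10 are named in the submitters' processing notes, without versions; the steps, thresholds, duplicate handling and the libraries that entered the peak call are not given in the sources used here. The name of the list mentions the batch, which the labels give for all 4 libraries, and the inhibitor, so the list may cover all groups or some. The record names carry the peak caller's name and a letter for each further summit of a region, per the file itself. Each record gives a region and a summit position. The deposited score is 10 times the −log10 q cut to a whole number, which was checked in every record. The deposited fold enrichment at the summit is a linear ratio to the expected background, as the authors' peak caller gave it. The authors' −log10 p and −log10 q values were at least 3.02 and 1.51. These are values of the peak, not of a sample, and were used only to describe, rank and filter peaks within the list.

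The 751 distinct fold values were whole numbers divided by 1 constant in 100% of records (tolerance 0.01). Each fold value occurred with a single p-value, and a Poisson tail with a mean of 7.63 gave the deposited −log10 p to within 7.9e-06 for the 106 values below 100. The fold at a summit is therefore its pileup plus 1, divided by the background plus 1, with the same background for every base. Whether the pileup counts fragments, single reads or read ends is not given in the sources used here. A single background means that differences in copy number or mappability between places were not divided out of the fold values. Exact Poisson 95% intervals were computed from the recovered pileups; for the lowest pileup, 17, the interval is 9.90 to 27.2, and for the median region, 42, it is 30.3 to 56.8. Copies of 1 molecule, or more than 1 count from the same fragment, would make these intervals too narrow.

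Gene positions and names came from a table of NCBI genes on GRCm38.p6, the assembly that mm10 represents, so both share coordinates. All 216 listed genes were found in it. The table gives the outer bounds of each gene but no strand, transcripts or exons. The planned window around transcription start sites was therefore replaced by a window of 1000 bp around either outer end, so a value can belong to the 3′ end, to a neighbour that shares the end, or miss an internal start site. For this reason the strongest summit anywhere in the gene was also computed. Regions were classed by their strongest summit as at a gene end, inside a gene or between genes. Regions not at a gene end were assigned to the nearest protein-coding gene end within 100 kb.

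The tests and 16 gene lists were fixed before the data were examined. For each list, the median fold at gene ends (0 without a summit) was ranked among 10000 random lists of the same size from the 21631 protein-coding genes, with ties split. A median at or beyond the 2.5th or 97.5th percentile was called apart. A median of 0 is the lowest possible and ranks midway among the random lists that are also 0. For lists of 10 or 14 genes this rank lay above the 2.5th percentile, so the lower limit could not be reached with the 1000 bp window. The ranking describes 1 peak list, since genes are not replicates. The rank of the number of members with a summit was added after the data were seen. Counts of regions away from gene ends were ranked among lists matched on gene length in 10 bins, also a comparison chosen after the data were seen. The rule for naming genes took all AP-1 genes and the 2 strongest members of each other list with those lacking a summit (the first 2 if over 5). It also took the 10 strongest distal regions with an AP-1 motif and the 5 genes with the most of them, which could not be applied. In their place the 5 genes with the most regions away from gene ends were taken, of which 1 is not reported here. This choice was made after the data were seen, as were those of the gene families, the Hox genes, the regions above 100-fold, the stretch on chromosome 1, Lgr5, Atp4a, Tjp3, Gna11, Myh9, Cd4, Itgam and Csf1r, and the genes named because another window raised their value. Sharing of reads with related gene copies was not tested for any gene. Because a genome sequence was not used here, 4 planned results could not be made: the AP-1 motif at summits against flanks, at distal against promoter summits, in strong against weak peaks, and near the gene lists.

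On simulated data made from the 21631 real genes, 200 genes were given a summit of 1000-fold within 1000 bp of an end. That is above every real value and inside the search window, so recovery was fixed in advance and checks the code only. All 200 were recovered, and the 26 further genes that received a planted summit were those with an end within 1000 bp of it. With the real values in place of simulated ones, 1 of 100 random lists of 14 genes fell outside the 2.5th to 97.5th percentiles. Since no list of this size could reach the lower limit, this count bears on the upper limit only. All 100 lists drawn from the 2000 strongest genes lay above the 97.5th. These 2000 genes were picked by the same values that were then ranked, so the latter result also checks the code only. Alternatives were windows of 500 and 2000 bp, −log10 q of at least 5 or 10, merged or joined regions, random lists matched on gene length, and the summit anywhere in the gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.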

Results

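Chromatin accessibility was profiled by bulk ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in mouse colonic organoids. Organoids are self-organising cultures of epithelial cells, here of the colonic epithelium. The design crossed the history of the donor (chronic colitis or healthy control) with a 24 h treatment (10 µM T-5224, a small-molecule inhibitor of the AP-1 transcription factor, or 0.1% DMSO as vehicle). Each of the 4 groups held 1 library. The question was how AP-1 inhibition alters transcription factor binding in organoids with and without a history of colitis. The values available for this were 1 list of peaks deposited for the series, with no value for a single library. Colitis was therefore not compared with control, and T-5224 was not compared with DMSO. Which libraries entered the peak call is not given in the sources used here, so the open chromatin described may be that of all 4 groups or of some of them. There are no replicates behind any value, so no p-value is given. Intervals are 95% intervals that cover counting error only. The depth of each library is unknown. The fold values imply an expected background pileup of 7.63 at any base, and a called summit had a pileup between 17 and 8197.

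The list held 113404 separate regions on the 19 autosomes and the X chromosome, with 157922 summits and 82.6 Mb of covered sequence. The median region was 481 bp wide (25th to 75th percentile, 330 to 851 bp), and 21.6% of regions had more than 1 summit. At the strongest summit of a region the authors' median fold enrichment over background was 4.99 (25th to 75th percentile, 3.13 to 11.0). Regions gathered sharply at the outer ends of genes: 9761 had their strongest summit less than 250 bp from the nearest end of a protein-coding gene, against 1621 when the same ends were moved by 50 kb. Of all regions, 18.8% (Wilson interval 18.6 to 19%) lay within 1000 bp of a gene end, 52.8% inside a gene and 28.4% between genes. Regions at gene ends were the stronger ones, with a median fold of 11.0, against 4.41 inside genes and 4.87 between them. When regions were ranked by fold and cut into 5 equal groups, 42.6% of the strongest group lay at a gene end, against 11.4% to 14.8% in the other 4.

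**Figure D1:**
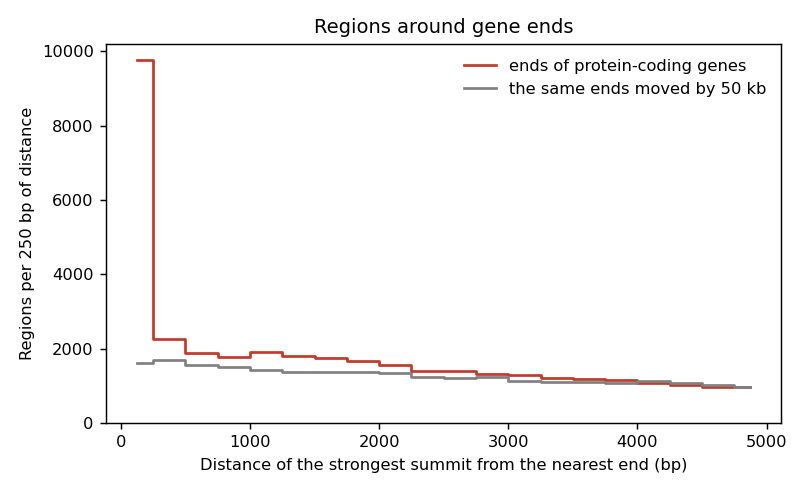
Number of regions (y axis, per 250 bp of distance) by the distance of the strongest summit from the nearest outer end of a protein-coding gene (x axis, bp), for the annotated ends (red) and for the same ends moved by 50 kb (grey). The first 250 bp hold 9761 regions for the annotated ends and 1621 for the moved ends.

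A summit lay within 1000 bp of an outer end in 13912 of 21631 protein-coding genes (64.3%, Wilson interval 63.7 to 65.0%), against 27.3% when the ends were moved by 50 kb. The share was 66.1% ± 5.59 (SD over 19 autosomes). Families were picked by the start of the gene symbol, so a set can hold genes of another function that share it. Most genes with symbols of the cytoplasmic ribosome had such a summit, 52 of 56 named Rpl and 39 of 44 named Rps. The same held for 76 of 78 with symbols of the mitochondrial ribosome and 37 of 40 with symbols of the proteasome. Few chemosensory receptor genes, which are used in sensory neurons, had one: 19 of 1110 olfactory receptor genes (1.71%, 1.10 to 2.66%) and 5 of 353 vomeronasal receptor genes. Among noncoding classes the share was 36.6% for lncRNA genes, 65.4% for tRNA genes and 8.19% for pseudogenes. Of the other families examined, 29 of 53 keratin genes, 12 of 22 UDP-glucuronosyltransferase genes and 2 of 70 defensin genes had such a summit. All these families were chosen after the data were seen. A summit at an end that genes share counts for each of them, so members need not have separate summits. The Ugt1a1 value is that of the 128-fold region described below, which need not reflect open chromatin.

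The genes of the AP-1 factor itself had the highest median of the 16 gene lists examined. Of 14 genes for AP-1 subunits and their dimer partners, 13 had a summit at an outer end, and the median fold was 48.9, higher than the medians of all 10000 random lists of 14 protein-coding genes, whose own median was 10.1. Jun (NCBI Gene 16476, chromosome 4, 95049036 to 95052222) had the highest value, 76.2-fold (70.5 to 82.2), at the end beside the noncoding gene Junos, followed by Atf3 with 72.5-fold (66.9 to 78.4). Junb followed with 59.9-fold (54.9 to 65.3) and Fos (NCBI Gene 14281, chromosome 12, 85473890 to 85477274) with 55.4-fold (50.6 to 60.6). The values were 54.3-fold at Mafk, 50.8-fold at Fosl2, 49.0-fold at Maff, 48.7-fold at Fosb and 35.9-fold at Fosl1. The intervals of Jun and Fos did not overlap, whereas those of Fos, Fosl2 and Fosb did. Lower values were found at Jdp2 (16.3-fold), Jund (15.4-fold), Batf2 (9.39-fold) and Batf3 (5.57-fold), and Batf had no summit at either end. The value at Jund was read at an end shared with Iqcn, and a summit inside the Jund gene reached 64.0-fold. Inside Batf, which encodes an AP-1 partner known from lymphocytes, the strongest summit was 15.3-fold.

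Away from gene ends, 111 regions had one of the 14 AP-1 genes as their nearest protein-coding gene within 100 kb. The median of 6.5 per gene lay above those of all 10000 random lists matched on gene length, whose median was 1. Jun had 23 such regions and Fosl2 had 22. Fos had 15, and the strongest of them, at chromosome 12, 85454264 to 85456316, reached 77.9-fold, above the 55.4-fold at the end of Fos itself. That region lies inside the annotated noncoding gene Gm38543. A further region on the other side of Fos, at 85484357 to 85488143, reached 64.6-fold. Junb had 1 such region, at 3.01-fold. Regions were placed by their strongest summit, so the count for Jund includes the 64.0-fold region already described, which spans the whole gene and both its ends.

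**Figure D2:**
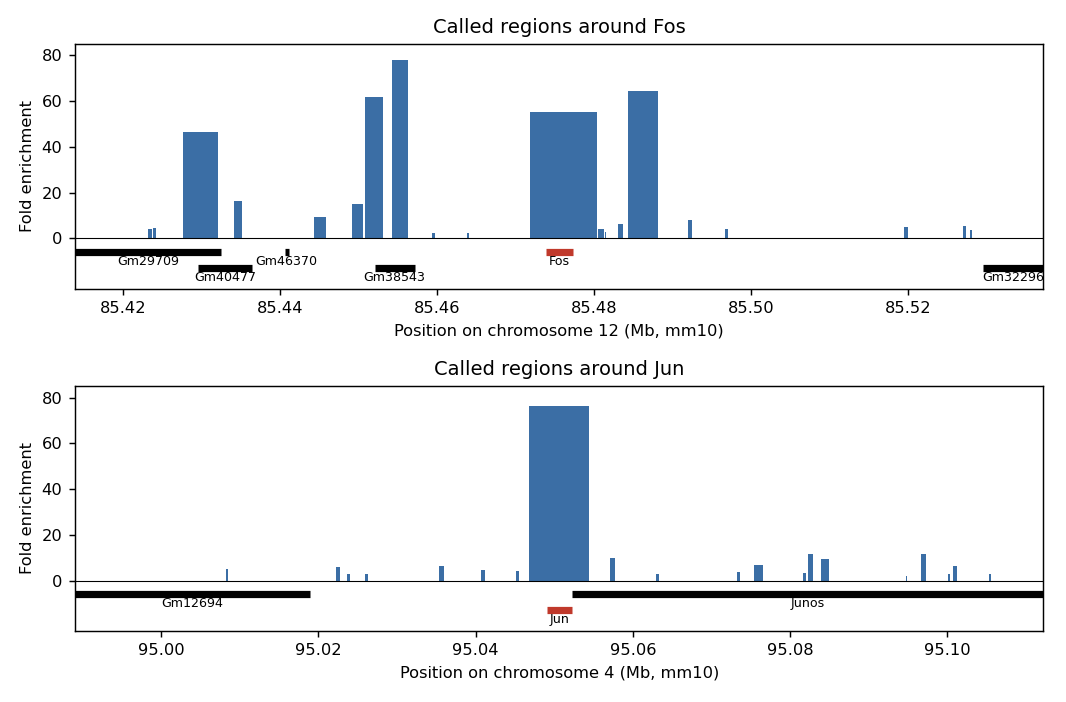
Called regions within 60 kb of Fos (upper panel) and Jun (lower panel). Each bar spans a region in mm10 coordinates (x axis, Mb) and its height is the authors' fold enrichment at its strongest summit (y axis); horizontal bars below 0 are annotated genes, with Fos and Jun in red. Beside Fos, at 55.4-fold, stand regions of 77.9-fold and 64.6-fold, while the region at Jun, at 76.2-fold, is the tallest in its window.

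Nearly all listed genes of colonic stem cells and of absorptive cells had a summit. In the stem cell and Wnt response list 15 of 16 genes had a summit at an end, with a median of 21.4-fold, at the 84.8th percentile of random lists. The strongest were Lrig1, a stem cell regulator of growth factor signalling, with 74.2-fold (68.6 to 80.2), and Ephb3, a receptor of the crypt base, with 71.3-fold (65.8 to 77.2). Axin2, a feedback inhibitor of Wnt signalling, had no summit at its outer ends but had one of 32.0-fold within the gene. Lgr5, the marker of crypt base stem cells, had 10.2-fold. In the absorptive colonocyte list 15 of 16 genes had a summit at an end and the median was 23.5-fold (89.4th percentile). The highest values at an end were those of Car2, a carbonic anhydrase, with 48.7-fold (44.2 to 53.6), and Cdx2, the intestinal homeobox factor, with 40.6-fold (36.4 to 45.1). Hnf4a, a nuclear receptor of the intestinal epithelium, had 23.4-fold, but 44.9-fold within 2000 bp of an end and 57.3-fold anywhere in the gene, above Car2. Slc9a3, a sodium-proton exchanger, had none at its ends and 34.8-fold within the gene. In both lists the number of genes with a summit lay above the 99th percentile of random lists, while the medians did not reach the 97.5th.

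The medians of the goblet, tuft and enteroendocrine lists were below that of random lists. Those of the goblet and tuft lists lay above the 2.5th percentile. The enteroendocrine median of 0 could not pass it, since it tied with every random list at 0. Of 12 goblet and secretory progenitor genes 7 had a summit at an end, and the median was 4.41-fold (26.6th percentile). The transcription factor genes Klf4 (48.8-fold) and Foxa3 (45.8-fold, at an end near Sympk) were the 2 strongest. The mucus genes Muc2, Tff3, Clca1 and Zg16 and the goblet factor Spdef had no summit at an end; anywhere in the gene, Clca1 reached 19.6-fold, Spdef 7.42-fold and Muc2 2.90-fold, and Tff3 and Zg16 had none, though Tff3 had 4.75-fold within 2000 bp of an end. Among 10 tuft cell genes 8 had a summit, and the median was 3.30-fold (22nd percentile), with Sh2d6 (15.9-fold) and Spib (8.58-fold, at an end near Mybpc2) strongest and none at Alox5ap and Il25. Anywhere in the gene, Sh2d6 had 40.5-fold and Spib 13.8-fold. Among 10 enteroendocrine genes 4 had a summit and the median was 0 (5.27th percentile), led by Chgb (11.1-fold) and Chga (6.03-fold), the genes of secretory granule proteins. The other 6, among them the lineage factors Neurog3 and Neurod1, had none at an end, and Neurog3 had none anywhere in the gene. Within 2000 bp of an end, Nkx2-2 had 8.0-fold, above Chga, and Neurod1 had 6.03-fold, the same as Chga.

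Genes linked to repair and inflammation were mixed. In the list of fetal-like and regenerative epithelial genes 15 of 17 had a summit at an end and the median was 26.2-fold (93.6th percentile). Anxa5 reached 73.4-fold (67.8 to 79.3), at an end near 1810062G17Rik, and Hbegf, an EGF receptor ligand, 53.8-fold (49.0 to 58.9). Il33 and Trp63 had no summit at an end, and their strongest summits within the gene were 26.6-fold and 9.51-fold. Of 16 genes of epithelial inflammation and host defence 13 had a summit, with a median of 7.88-fold (40.7th percentile). The feedback inhibitors of NF-κB signalling Nfkbia (54.0-fold, 49.2 to 59.2) and Tnfaip3 (46.7-fold, 42.3 to 51.5) had the highest values at an end, whereas the antimicrobial lectin genes Reg3b and Reg3g and the calprotectin gene S100a9 had none. Anywhere in the gene, Nfkbiz had the highest value, 62.4-fold (57.2 to 67.9). Of 14 interferon response and antigen presentation genes 12 had a summit, with a median of 16.8-fold (71.8th percentile). B2m, the light chain of MHC class I, had 47.8-fold and Irf9 had 35.1-fold, at an end near Rnf31. Ifit3 and Ciita had no summit at an end, and Ciita, the activator of MHC class II genes, had 14.6-fold within the gene.

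Every one of the 13 DNA replication and cell cycle genes had a summit at an end, with a median of 44.6-fold (99.98th percentile of random lists). Ccna2, cyclin A2, had 71.9-fold and Pcna, the sliding clamp of replication, 61.6-fold, at an end near Cds2. The 12 ubiquitously used genes, all with a summit, had a median of 43.5-fold (99.9th percentile), led by Rpl13a (68.5-fold) and Polr2a (55.8-fold). Within 2000 bp of an end, Actb had 59.4-fold, above Polr2a. Their range of 22.6 to 68.5-fold overlapped that of the AP-1 genes. All 10 colon cancer genes had a summit, with a median of 33.8-fold (97.1st percentile) and the highest values at Fbxw7 (62.3-fold) and Trp53 (49.6-fold, at an end near Wrap53). Anywhere in the gene, Tcf7l2 had 56.6-fold, above Trp53.

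Genes of small intestine and stomach and of leukocytes had fewer summits than most random lists. Only 2 of 14 genes of small intestine and stomach had one at an end, Rbp2 with 8.0-fold and Sis, the brush border sucrase-isomaltase, with 3.59-fold. None of the 10000 random lists had so few. The 12 without one included Gata4, the factor of the proximal intestine, and Fabp6, although Gata4 had 13.7-fold and Atp4a 26.4-fold within the gene. Of 14 leukocyte genes 5 had a summit, Spi1 (25.7-fold) and Cd68 (21.8-fold, at an end near Eif4a1) being the strongest, and the 9 without one included Ptprc and Cd3e. That number lay at the 1.92nd percentile of random lists. Within 2000 bp of an end, Cd68 had 41.0-fold and Cd79a, without a summit within 1000 bp, had 21.0-fold. Neither gene was assigned a region away from gene ends, so both summits belong to regions at or nearer to an end of another gene. Among 14 fibroblast, endothelial and muscle genes 7 had a summit, led by Col1a1 (16.3-fold) and Myh11 (6.84-fold), and the 7 without included Col1a2 and Col3a1. Anywhere in the gene, Pdgfra (8.81-fold) and Cdh5 (8.35-fold) were above Myh11. Among 14 genes of neuron, heart and liver 8 had one, led by Tnnt2 (22.3-fold) and Apoa2 (11.2-fold), and the 6 without included Rbfox3 and Gad2. The order changed with the summit anywhere in the gene, where Apoa2 had 64.5-fold and Syt1 32.7-fold, in the range of the AP-1 genes. The Apoa2 summit belongs to a region at or nearer to an end of another gene, since no region away from gene ends was assigned to Apoa2. The medians of these lists were 1.33-fold (10.9th percentile) and 2.78-fold (16.6th), within the range of random lists. Medians were 0 for the small intestine and stomach list (4.11th percentile) and the leukocyte list (4.35th). That is the lowest possible median and ties with every random list at 0, so neither list could pass the 2.5th.

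**Figure D3:**
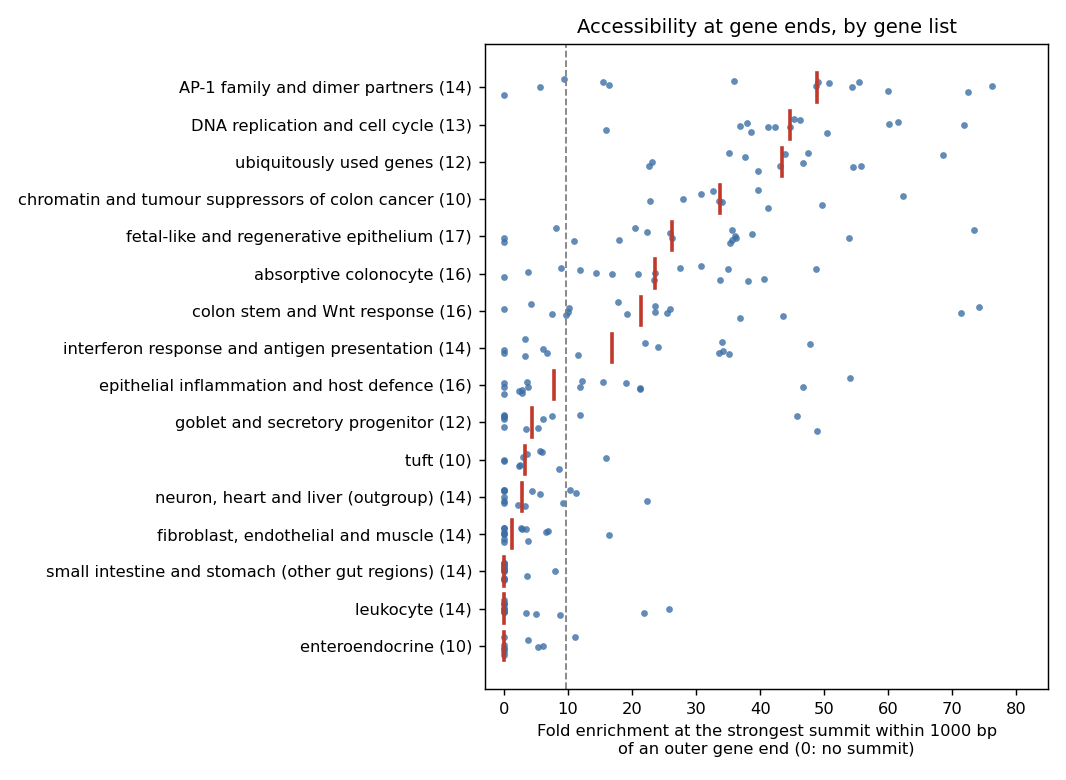
Fold enrichment at the strongest summit within 1000 bp of an outer gene end (x axis; 0 means no summit) for each gene (blue points) of the 16 lists (y axis, number of genes in brackets). Red bars mark list medians and the dashed line the median of all protein-coding genes, 9.62; medians run from 0 for 3 lists to 48.9-fold for the AP-1 genes.

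Beyond gene ends, 92089 regions remained, and 88.3% of them had a protein-coding gene end within 100 kb. Pdlim5, which encodes a PDZ and LIM domain protein, had the most, 72. It was followed by Shroom3, a regulator of epithelial cell shape, and Fat1, an atypical cadherin, with 69 each. Lmo7 had 65, where the median protein-coding gene had 2. These 4 genes are over 100 kb long. Relative to genes of like length, several lists had high counts. The median number per gene was 14.5 for the stem cell list, 13.5 for absorptive colonocytes and 11 for the fetal-like list, each above all 10000 random lists. It was 4 for the inflammation list (99.99th percentile), 4.5 for the goblet list (99.3rd) and 12 for the colon cancer list (99.6th). These 3 each fell below the 97.5th under 1 or more alternatives, to the 96.1st, 96.5th and 95.9th. The leukocyte list had a median of 0, at the 2.07th percentile, but at the 3.42nd when only regions within 25 kb were assigned. A median of 0 is the lowest possible, so these 2 percentiles differ only by how many random lists were also at 0. Genes with distant neighbours can be assigned more regions, which was not matched. Joining regions whose edges lay within 12.5 kb gave 31292 clusters, of which 13747 held a single region. The cluster with the most, 137 regions, spanned chromosome 10, 81217265 to 81606900, and overlapped 26 protein-coding genes, among them Tjp3 and Gna11. A cluster of 93 regions lay over Myh9 on chromosome 15 and overlapped 3 protein-coding genes.

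The strongest regions lay largely away from protein-coding gene ends. Of 14 regions above 100-fold, 3 (21.4%, Wilson interval 7.57 to 47.6%) were within 1000 bp of a protein-coding gene end, against 83 of the 100 next strongest regions (83.0%, 74.5 to 89.1%). The highest value, 950-fold, was in a region of 6143 bp at chromosome 17, 39842843 to 39848985, next to the ribosomal RNA pseudogene Rn18s-rs5. The next, 911-fold, was at chromosome 2, 98666082 to 98667457, over 1 Mb from the nearest protein-coding gene. A pair of these regions lay on chromosome 1 at Hjurp (163-fold, 155 to 172) and Ugt1a1 (128-fold, 121 to 136), in a stretch from 88211452 to 88310538 of which 81.4% was called, against 6.85% of the 50 kb below it and 1.23% of the 50 kb above. The fold values are not corrected for copy number, so these calls need not reflect open chromatin.

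**Figure D4:**
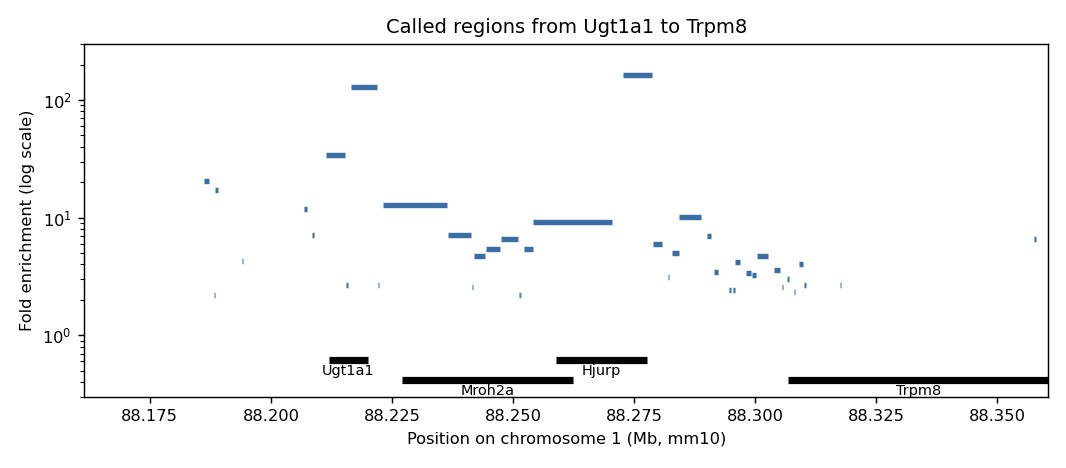
Called regions on chromosome 1 in and within 50 kb of the densely called stretch (x axis, Mb, mm10), each drawn as a line at the authors' fold enrichment of its strongest summit (y axis, log scale); black bars below 1 are the 4 named genes. Regions fill 81.4% of the stretch from Ugt1a1 to the lower end of Trpm8, with the highest values, 128-fold and 163-fold, at Ugt1a1 and Hjurp.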

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

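The 113404 regions fell to 68783 with a −log10 q of at least 10 and stayed within 1.5 times the reported count under the other 4 settings tried (90796 to 157922). The share of protein-coding genes with a summit at an end was 59.7% within 500 bp, 68.8% within 2000 bp, 58.7% at the stricter q, 56.3% when a region had to overlap the end itself, and 27.3% with the ends moved by 50 kb, a check added after the data were seen. The share of regions at gene ends was 13.8% for protein-coding genes alone, 13.7% within 500 bp, 27.8% within 2000 bp and 22.8% at the stricter q. Clusters rose from 31292 to 52993 with edges within 5000 bp. The AP-1, cell cycle and ubiquitously used lists stayed above the 97.5th percentile under all 4 settings tried. The fetal-like list reached the 99.2nd percentile within 2000 bp and the 98.1st with the summit anywhere in the gene, but the 91.3rd with lists matched on gene length and the 93.6th at the stricter q. The inflammation list crossed the middle, at the 52.4th (2000 bp), 57.2nd (lists matched on gene length) and 56.6th (anywhere in the gene) percentiles, but not at the stricter q (33.6th). Within 2000 bp the leukocyte list was at the 2.1st percentile and the small intestine and stomach list at the 1.84th. With the summit anywhere in the gene these were at the 0.335th and 0.925th percentiles, the fibroblast, endothelial and muscle list at the 0.46th and the neuron, heart and liver list at the 2.405th. The leukocyte and the small intestine and stomach lists were at the 2.555th and 4.425th percentiles with lists matched on gene length. At the stricter q they were at the 8.995th and 8.865th. Both lists had a median of 0, the lowest possible, under all these settings. Their percentiles therefore follow the number of random lists also at 0 and show no change in the lists' own medians. For regions away from gene ends, assignment within 25 kb put the goblet list at the 96.535th percentile, the colon cancer list at the 95.86th and the leukocyte list at the 3.42nd, all no longer past their limits. The leukocyte median stayed at 0, so its move follows the random lists at 0. Assignment within 25 kb moved the fibroblast list to the 47.995th, the neuron list to the 62.465th and the cell cycle list to the 31.24th. Random lists not matched on length put goblet genes at the 96.595th and inflammation genes at the 96.145th, no longer past the limit, and moved the enteroendocrine list to the 43.06th, the ubiquitous list to the 43.505th and the neuron list to the 60.245th. The AP-1, stem cell, colonocyte and fetal-like lists stayed above the 97.5th under both. The cause of the moves of lists with a median above 0 was not tested. For the lists, all settings but 2000 bp were added after the data were seen. For single genes, 31 of 216 end values left their interval within 2000 bp and 57 with the gene-wide summit. Random lists matched on promoter CpG content and all motif alternatives were not run. No paired analysis was possible because each group has 1 library and the list holds no value for a single library.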

Other observations

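All tests of explanations in this part were chosen after the patterns had been seen. The Hox genes, which encode position along the body axis, differed in value between their clusters. In the HoxA cluster 10 of 11 genes had a summit at an end, with a median of 20.2-fold and the highest value, 46.5-fold (95% Poisson interval 42.1 to 51.3), at Hoxa5. In HoxB 9 of 10 did, with a median of 6.90-fold, and Hoxb9 (23.0-fold) and Hoxb13 (20.8-fold) had the highest values. In HoxD 8 of 9 did, at a median of 6.61-fold and at most 10.8-fold, at Hoxd3. In HoxC 3 of 9 did, none above the 4.75-fold of Hoxc5. Genes of a cluster lie side by side, so an end can be shared between neighbours, and the clusters were not tested against each other.

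The X chromosome lay outside the range of the autosomes in 3 quantities. It held 12.9 regions per Mb, against 47.0 ± 7.64 (SD, 19 autosomes, lowest 35.7), and 38% of its protein-coding genes had a summit at an end, against 53.9% to 72.7% on the autosomes. Where there was one, the median was 16.1-fold, against 26.7 ± 1.28 (lowest autosome 23.7). Over all its regions the median fold was 5.10, against 4.99 ± 0.125. All called regions had to pass the same cut, so this similar median does not show equal signal. The fold values are not corrected for copy number, and a copy number difference of the X chromosome was not tested.

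On chromosome 1, 33 regions covered 81.4% of the 99.1 kb from Ugt1a1 to the lower end of Trpm8, against 3.23% of the spanned genome. The ends of Hjurp and Ugt1a1 ranked 2 and 3 among all protein-coding genes. In the 29090 bp between Hjurp and Trpm8, where no gene is annotated, 63.8% was called, rank 5 of 7544 such gaps of 20 to 50 kb, whose median was 0.839%. The stretch was picked out for its dense calls, so this rank is no independent test. A higher copy number of the stretch was not tested and stays open, since the fold values use 1 background for every base.

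The 14 regions above 100-fold do not resemble strong promoters as a set. A candidate explanation, open promoters of protein-coding genes, is argued against for the set as a whole, since 21.4% lay at a protein-coding gene end (Wilson interval 7.57 to 47.6%), below the lower bound of 74.5% for the 100 next strongest regions. The 3 exceptions lay at ends of Lars2, Hjurp and Ugt1a1, and no strand was used, so these ends need not be gene starts. Those of Hjurp and Ugt1a1 lie in the densely called stretch on chromosome 1, where calls need not reflect open chromatin. Reads of repeated sequence gathered at 1 copy stay open as an explanation and were not tested, since no genome sequence was used. The groups of the design were not tested as an explanation, since no library can be told from another.

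Of the leukocyte genes, 2 had a summit above 10-fold at an end, Spi1 and Cd68. Lower values at an end were found at Cd4 (8.81-fold, at an end near Gpr162), Itgam (4.99-fold) and Csf1r (3.48-fold), and 8 of the 14 genes had no summit anywhere in the gene. An end shared with a neighbouring protein-coding gene may account for Cd68, which lies beside Eif4a1. It does not account for both, since only 1 of the 2 summits had such an end within 1000 bp. Ends of noncoding genes and ends farther away were not searched. The summit of Spi1 lay at its higher end, and whether that is the start of the gene is open, since no strand was used here. Leukocytes in the cultures were not tested as an explanation and stay open.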
